A study of Mus musculus with 2 samples.

How the data were processed

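Total RNA of 2 mouse samples was labelled with Cy3 and hybridised to Agilent one-colour expression arrays, per the labels. The sample groups, neurosphere and VZ/SVZ, were taken from the sample titles, with 1 array each. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12, per the file headers, whereas the submitters' processing notes name version 9.1. The processed signal used here is an intensity after background subtraction, per the file headers, and is not scaled between arrays. The authors' deposited value table held the same intensity values: the ratio to the scanner value was 1.00 at the median and lay between 0.998 and 1.002 from the 5th to the 95th percentile of probes on the neurosphere array. Its column medians were 12.95 and 18.55, on a linear scale and neither centred nor scaled between arrays. Both arrays share 1 slide and 1 scan time, so slide and scan do not separate the groups.

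Each array held 62976 spots, of which 3671 control spots were left out. Spots marked by the scanner software as non-uniform or as population outliers were also left out, 79 on the neurosphere array and 142 on the VZ/SVZ array; the plan named the non-uniform spots. The level of a probe was log2 of its processed signal minus the 75th percentile of these log2 probe values on its array. Taken over spots instead, the 75th percentile of the signal was 134.3 for the neurosphere and 139.9 for VZ/SVZ. Replicate spots of a probe were averaged on the log2 scale; their SD was 0.05 on the neurosphere array and 0.05 on the VZ/SVZ array. No probe was saturated. Depth on an array is signal over background: the lowest level among probes well above background was -4.26 on the neurosphere array and -4.16 on the VZ/SVZ array, and differences below those levels are known as bounds.

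Of 56599 probes, 32991 were named by accession through RefSeq's mouse gene table (assembly GRCm38.p6, used for names), 10222 by symbol and 520 by synonym, and 12866 kept the name in the scanner files. Coordinates are those of the scanner files (mm9). A gene took the probe with the highest mean level over both arrays among its probes well above background on at least 1 array. In 7075 genes with several such probes, the median SD between probes of a gene was 0.38, and 243 genes had probes that differed by 2-fold or more in opposite directions. Genes with no probe well above background on either array were not compared. A gene dim on 1 array was given a bound, computed from the higher of its own dim level and the lowest level among probes well above background on that array. Probe sequences were not used here.

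Because each group has 1 array, no test was made. Genes were counted at a fixed size of 2-fold. For each gene list the median difference was ranked among 10000 random lists of the same size drawn from 20 level bins, with a 95% bootstrap interval of the median over members from 2000 resamples. The design, the gene lists and the rule for named genes were written before the data were examined. The lists cover neural stem, transit-amplifying, neuroblast, neuron, oligodendrocyte, astrocyte, ependymal, choroid plexus, microglia, endothelial, mural, fibroblast and erythrocyte markers; mitosis, DNA replication and cyclin-dependent kinase inhibitors; FGF and EGF feedback, Notch, Wnt, Hedgehog, BMP and TGF-beta, immediate early, glycolysis, cholesterol, interferon, reactive glia, matrix, forebrain regional, polycomb, sex-linked and ribosomal protein genes. Lists of posterior patterning, anterior patterning and fibroblast genes were added after the main results were seen.

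The genes named are Ecrg4, up to 4 members of each list with the largest absolute difference and any member opposing its list by 2-fold or more, the 15 genes with the largest difference in each direction among those bright on both arrays, and the 8 with the largest bound in each direction. The 15 and the 8 were ranked among genes with a named symbol, leaving out clone, Riken, Gm, LOC and accession names. Genes named as not well above background, Aurkb and the members of the added lists fall outside that rule and were chosen after their values were seen. Some planned results for single genes are not reported here.

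The steps were tested on simulated arrays of 27183 genes. Both simulated arrays took the VZ/SVZ levels with noise from the scanner's error model only. They hold no spread between animals, cultures or labellings, so they give no rate of false calls for the real arrays. All 50 genes simulated at a log2 difference of 1.5 and all 50 at 3 were recovered at 2-fold in the right direction, as were 47 of 49 at -1.5 and 43 of 49 at -3, and 41 of 26965 unchanged genes passed 2-fold. Of 31 lists not shifted in the simulation, 2 fell outside percentiles 2.5 to 97.5.

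The alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), quantile normalization, scaling to the median of probes bright on both arrays, the authors' deposited values, other filters on dim probes, the median over a gene's probes, outlier spots kept, a 4-fold threshold, lists without shared genes and random lists not matched on level. Scaling to spike-in probes was planned and not run. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.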

Results

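Total RNA from β-galactosidase-positive mouse brain cells was measured on 2 one-colour Agilent expression arrays, 1 from a neurosphere culture and 1 from the ventricular and subventricular zone (VZ/SVZ), the germinal layer that lines the lateral ventricles. A neurosphere is a floating cluster that neural stem and progenitor cells form in serum-free medium with growth factors. Per the labels, both samples came from 6-month-old C57BL/6 mice heterozygous for Ecrg4, and the growth protocol places both cell samples in medium with bFGF, EGF and heparin; the time in culture and the way positive cells were picked are not given in the sources used here. Of 56605 probes, 34620 (61.2%) were well above background on the neurosphere array and 37477 (66.2%) on the VZ/SVZ array. No spot was saturated. Probes well above background on both arrays numbered 32392, and their levels had a Pearson r of 0.911 across probes, which are not independent replicates. With 1 array per group there are no replicates: the number of arrays limits the precision, no p-value is given, and every difference describes these 2 arrays. Differences are log2 levels in VZ/SVZ minus neurosphere, so a negative value means a higher level in the neurosphere. The error after ± is the technical error from the scanner's error model and does not cover the spread between animals or cultures. Its median was 0.21 over probes well above background on both arrays. The fold of a gene with several probes is that of its brightest probe, and the values of other probes are given for some genes only. Normexp moved 155 of the differences of named genes by more than their technical error and 34 by less.

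The first comparison asked how the targeted gene stood in the samples. Ecrg4, which encodes the secreted peptide precursor augurin and carries the targeted allele in both samples, was 11-fold lower in VZ/SVZ than in the neurosphere (log2 difference -3.46 ± 0.21). Its processed signal was 351.1 on the neurosphere array and 34.0 on the VZ/SVZ array, well above background on both. It was measured by 1 probe, at chromosome 1, 43799321 to 43799380 (mm9). The position of the targeted part of the gene relative to this probe is not given in the sources used here, so the value does not check the genotype, which the labels give as the same in both samples. With background corrected by normexp the difference of Ecrg4 was smaller, -2.21, in the same direction. Where a gene was dim on 1 array, in what follows, "at least" gives the bright level over the higher of the dim value and the lowest level among probes well above background on the dim array.

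Across the 26434 genes measured, 4934 were at least 2-fold higher in VZ/SVZ, 2927 were at least 2-fold higher in the neurosphere, and 18573 lay within 2-fold. Among genes with a named symbol and bright on both arrays, the largest differences towards VZ/SVZ were in Crabp1, a retinoic acid binding protein (540-fold, 9.08 ± 0.23), Spp1, the secreted matrix protein osteopontin (526-fold, 9.04 ± 0.21), Bag3, a co-chaperone (330-fold, 8.37 ± 0.32), and Thbs1, the matrix glycoprotein thrombospondin (320-fold, 8.32 ± 0.33). S100a6, Tgfbi, Inhba and Dio2 followed at 180-fold to 203-fold. Towards the neurosphere the largest were Car3, a carbonic anhydrase (172-fold, -7.43 ± 0.25, with another of its probes at -0.00), Cacng5, an auxiliary subunit of ion channels (105-fold, -6.71 ± 0.27), Crispld2 (88.8-fold, -6.47 ± 0.25) and Pou3f1, a POU-domain transcription factor (64.3-fold, -6.01 ± 0.22). The transcription factor genes Irx1, Irx2 and Hoxa3 and the Wnt receptor gene Fzd9 were 26.1-fold to 39.5-fold higher in the neurosphere. Patj also stood among these genes (-4.60), but its probes pointed in both directions, from -4.60 to 1.56. Among genes dim on the neurosphere array, the matrix protease gene Mmp3 was at least 1137-fold and the BMP antagonist gene Grem1 at least 919-fold higher in VZ/SVZ. Among genes dim on the VZ/SVZ array, Fzd10, another Wnt receptor gene, was at least 96.5-fold and Gbx2, a homeobox gene of the hindbrain and midbrain boundary, at least 39.8-fold higher in the neurosphere.

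The counts depended on how signal near background was treated and on the scaling. Of the 4934 genes higher in VZ/SVZ, 1773 were dim on the neurosphere array, against 390 of the 2927 genes higher in the neurosphere that were dim on the VZ/SVZ array. With normexp the counts were 1470 and 1268. Genes higher in VZ/SVZ made up 62.8% of the calls with the main scaling, 53.7% with normexp and 51.9% with quantile normalization (3908 against 3629). Quantile normalization gives both arrays the same distribution of levels, which by construction favours counts near balance.

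**Figure D1:**
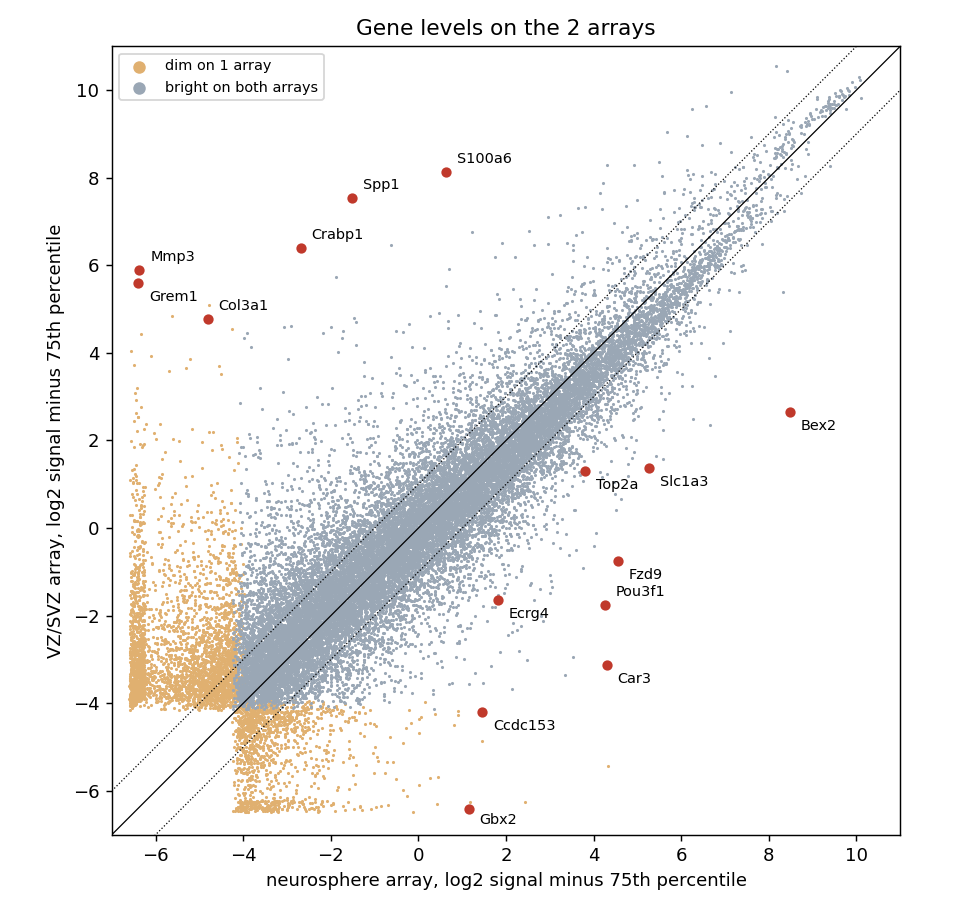
Normalised log2 level per gene on the neurosphere array (x axis) and the VZ/SVZ array (y axis), relative to each array's 75th percentile, for genes well above background on both arrays (grey) or on 1 (orange, at measured levels), with dotted lines at 2-fold and some of the named genes in red. Spp1 and Crabp1 lie far above the diagonal of equal levels, and Ecrg4 lies below it by 3.46.

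Genes of cell division were lower in VZ/SVZ as a group. Of 24 mitosis genes, 23 were at least 2-fold higher in the neurosphere and only Aurkb lay within 2-fold; the median was -2.03, or 4.08-fold. Ccna2, the cyclin of S phase and G2, was 7.02-fold higher in the neurosphere (-2.81 ± 0.21, with another probe at -1.23). Top2a, which untangles replicated DNA, was 5.67-fold higher there (-2.50 ± 0.20, with another probe at -0.96). Of 24 DNA replication genes, 20 were at least 2-fold higher in the neurosphere and none in VZ/SVZ, with a median of -1.55 (2.92-fold); the polymerase subunit gene Pola1 (-2.25 ± 0.21) and the thymidine kinase gene Tk1 (-2.23 ± 0.21, with another probe at 0.95) led them. Each list's median was set against 10000 random lists of the same size and matched levels, as a description of these arrays, and both medians lay below every random list. The 95% bootstrap intervals over members were -2.31 to -1.70 for mitosis and -1.83 to -1.25 for replication. Among 17 cyclin-dependent kinase inhibitors and p53 targets the median was -0.23 and the mean 0.13, at percentile 63.7, with 3 genes higher in VZ/SVZ and 3 higher in the neurosphere. Cdkn1c, which encodes the inhibitor p57, was at least 25.2-fold higher in VZ/SVZ, whereas Cdkn2d and Cdkn1b were 3.25-fold and 2.46-fold higher in the neurosphere, Cdkn1b with another probe at -0.79.

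Cholesterol synthesis genes were also lower in VZ/SVZ. Of 20 measured, 10 were at least 2-fold higher in the neurosphere, among them Hmgcs1 (3.09-fold, -1.63 ± 0.20) and Dhcr7, the last enzyme of one branch of the pathway (2.93-fold, -1.55 ± 0.20). The list median was -0.98 and lay below every random list. Feedback genes of FGF and EGF receptor signalling had a median of -0.78 at percentile 0.39, with 6 of 16 higher in the neurosphere. Spry1, an inhibitor of receptor tyrosine kinase signalling, was 3.63-fold higher there (-1.86 ± 0.20) and the transcription factor gene Etv5 3.32-fold higher (-1.73 ± 0.20). Il17rd was at -1.71, with its probes running from -1.71 to 1.39. Errfi1, a feedback inhibitor of EGF receptors, had the opposite direction and was 10.5-fold higher in VZ/SVZ (3.39 ± 0.20, with another probe at 0.85). The bootstrap interval of this list's median reached 0.07, and with the median over a gene's probes the percentile was 3.91. All 29 measured genes for cytosolic ribosomal proteins lay within 2-fold, with a median of -0.60 at percentile 1.11; the percentile was 6.93 with the median over a gene's probes. Glycolysis and hypoxia genes had a median of 0.17 at percentile 95.6, and 4 of 20 were higher in VZ/SVZ, led by Ndrg1 (14.8-fold, 3.89 ± 0.21) and Vegfa (6.37-fold, 2.67 ± 0.20).

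Stem and progenitor markers divided between the samples. Of 19 neural stem and radial glia-like genes, 6 were higher in the neurosphere and 2 in VZ/SVZ, with a median of -0.50 at percentile 6.54. Nes, the intermediate filament gene used as a progenitor marker, was 3.51-fold higher in the neurosphere (-1.81 ± 0.20), as was the fatty acid binding protein gene Fabp5 (6.58-fold, -2.72 ± 0.20). The glutamate transporter gene Slc1a3 was 15-fold higher there by its brightest probe (-3.90 ± 0.20), but its probes ran from -3.90 to 0.74. Id4 and Prom1 were 2.46-fold and 2.04-fold higher in VZ/SVZ. Among 12 transit-amplifying progenitor genes (median -0.19, percentile 27.3), Olig2 was 3.46-fold higher in the neurosphere and Dlx2 6.66-fold higher in VZ/SVZ. Polycomb, chromatin and self-renewal genes had a median of -0.49 at percentile 3.64, with 5 of 18 higher in the neurosphere and 4 in VZ/SVZ; Cbx2 was at least 5.56-fold higher in the neurosphere, and Lin28a was 6.24-fold higher in VZ/SVZ, with another probe at 0.63.

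Neuronal genes were higher in VZ/SVZ in part. Of 17 mature neuron genes, 8 were at least 2-fold higher in VZ/SVZ and 3 in the neurosphere, and the median of 0.76 lay at percentile 98.6. The opioid precursor gene Penk was at least 118-fold higher in VZ/SVZ, with another probe at 3.08, the neurofilament gene Nefm at least 77.9-fold, and Thy1 48.5-fold (5.60 ± 0.25), while Stmn3 was 3.93-fold higher in the neurosphere. Rbfox3 and Slc17a7, other genes of this list, were not well above background on either array. The bootstrap interval ran from -0.12 to 4.04, and the percentile was 79.6 over genes bright on both arrays and 96.7 with normexp. Among 16 neuroblast genes (median 0.46, percentile 94.4), 5 were higher on each side: Dpysl3 (22.4-fold, 4.49 ± 0.21), Gad2 (8.51-fold, 3.09 ± 0.20, with another probe at 0.54) and Tubb3 (3.72-fold, 1.90 ± 0.21) in VZ/SVZ, and Sox11 (4.26-fold, -2.09 ± 0.20) and Stmn1 (2.67-fold, -1.42 ± 0.20) in the neurosphere. Dorsoventral forebrain factors had a median of 0.32 at percentile 80.2, with 4 of 19 higher in VZ/SVZ, among them Tfap2c at least 12.7-fold (another probe at 1.31) and Nkx2-1 3.60-fold (another probe at 4.16). Otx2 was 2.59-fold higher in the neurosphere, with another probe at -0.43.

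Glial markers moved apart within each class. Of 17 astrocyte genes, 8 were higher in the neurosphere and 5 in VZ/SVZ. The angiotensinogen gene Agt was at least 17.5-fold higher in the neurosphere, while the folate enzyme gene Aldh1l1 was 23.0-fold (4.52 ± 0.21, with another probe at 2.51) and Sparcl1 10.4-fold (3.38 ± 0.06) higher in VZ/SVZ. The astrocyte median was -0.66 at percentile 0.42, but its interval ran from -1.92 to 1.78, and over genes bright on both arrays the median was 0.28 at percentile 94.7. Of 10 oligodendrocyte progenitor genes (median 0.26, percentile 78.8), Pdgfra was at least 75.5-fold higher in VZ/SVZ, with another probe at 1.14, and Lhfpl3 was 5.09-fold higher in the neurosphere; across the scaling and background alternatives this median lay between -0.19 and 0.26. Of 15 myelinating oligodendrocyte genes (median 0.30, percentile 64.6), 4 were higher in VZ/SVZ, led by the lipocalin gene Apod (136-fold, 7.09 ± 0.06). In the neurosphere 3 were higher, among them the transferrin gene Trf (5.53-fold, -2.47 ± 0.20). Gpr17 and Neu4 of the progenitor list and Opalin and Fa2h of the myelinating list were not well above background on either array. Which cells gave the signal of any of these genes was not measured.

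None of the 21 ependymal and motile cilia genes was 2-fold higher in VZ/SVZ, and 5 were higher in the neurosphere, Ccdc153 by at least 49.0-fold, the ciliary dynein gene Dynlrb2 by 7.45-fold (-2.90 ± 0.23), Rfx3 by 5.30-fold (-2.41 ± 0.20, with another probe at 0.24) and Foxj1, the regulator of motile cilia, by 4.11-fold (-2.04 ± 0.21) among them. The median of -0.36 lay at percentile 2.37, near the limit of 2.5, and was not outside it with normexp (18.2), over genes bright on both arrays (10.1), with the authors' deposited values (2.66), with outlier spots kept (2.5) or against random lists not matched on level (4.38). Of 12 choroid plexus genes, 5 were higher in VZ/SVZ, led by the water channel gene Aqp1 (123-fold, 6.94 ± 0.34) and Enpp2 (13.3-fold, 3.74 ± 0.22, with another probe at -0.10), and Otx2 was higher in the neurosphere; the median was 0.88 at percentile 96.2, and 0.16 with normexp. Ttr, Kl, Kcne2 and Slc4a5 of the same list were not well above background on either array. Among microglia and macrophage genes, 13 of 20 were measured (median 0.72, percentile 95.2), with Laptm5 at least 4.49-fold and Trem2 at least 3.80-fold higher in VZ/SVZ and Pf4 at least 5.92-fold higher in the neurosphere. Cx3cr1, P2ry12, C1qa and Tyrobp were not well above background on either array. The 3 measured erythrocyte genes were all within 2-fold (median 0.10, percentile 37.2; from -0.31 to 0.10 across scaling and background alternatives).

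Mesenchymal and vascular markers and genes of BMP and TGF-beta signalling were mostly higher in VZ/SVZ, and genes of matrix and inflammation were higher there in part. Of 14 meningeal fibroblast and collagen genes, 10 were at least 2-fold higher in VZ/SVZ, with a median of 4.0 (16-fold) above every random list and an interval of 1.20 to 7.17; with normexp the median was 1.72. The small proteoglycan genes Dcn and Lum were at least 413-fold and 241-fold higher, and the collagen genes Col3a1 and Col1a1 at least 526-fold and 280-fold, Col3a1 with another probe at 0.91 and Col1a1 at 5.33. Slc6a13 and Igfbp2 had the opposite direction, at least 14.0-fold for Slc6a13 and 3.48-fold for Igfbp2. Of 16 endothelial genes, 12 were higher in VZ/SVZ (median 1.98, above every random list; 0.89 with normexp), including the adhesion gene Cdh5 at least 72.9-fold and the tight junction gene Cldn5 20.3-fold (4.34 ± 0.29), whereas Flt1 and Ramp2 were 8.77-fold and 2.91-fold higher in the neurosphere, Flt1 with another probe at -0.77. Of 13 mural cell genes, 7 were higher in VZ/SVZ and none in the neurosphere, with Pdgfrb at least 176-fold and Rgs5 18.1-fold (4.18 ± 0.24); the median of 1.03, 0.30 with normexp, lay at percentile 99.8, and at 96.8 over genes bright on both arrays.

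Among 20 BMP and TGF-beta genes, 11 were higher in VZ/SVZ, and the median of 1.26 (2.39-fold) lay above every random list; with normexp it was 0.34. Grem1 was at least 919-fold higher, Bmp4 38.4-fold (5.26 ± 0.25) and Tgfb1 5.78-fold (2.53 ± 0.32). Id2 was the exception at -1.03, with its probes at -1.03 and 1.92. Reactive glia and inflammation genes had a median of 0.93 at percentile 99.95, with 10 of 20 higher in VZ/SVZ, among them Spp1, the heat shock gene Hspb1 (42.8-fold, 5.42 ± 0.30) and the lectin gene Lgals3 (35.0-fold, 5.13 ± 0.28). The chemokine gene Cxcl10 (5.52-fold) and the ceruloplasmin gene Cp (2.85-fold) were higher in the neurosphere, and the interval ran from -0.08 to 1.64. Matrix and adhesion genes of the niche had a median of 0.31 at percentile 98.95, with 8 of 20 higher in VZ/SVZ: Col4a1 12.6-fold (3.65 ± 0.20), Lama1 at least 10.9-fold and Nid1 9.76-fold (3.29 ± 0.20), all of basement membranes. Bcan, a proteoglycan gene of brain matrix, was 17-fold higher in the neurosphere (-4.08 ± 0.21, with another probe at -2.53). The interval of this list ran from -0.53 to 2.72, and against random lists not matched on level the percentile was 83.8. Immediate early genes had a median of 0.71 at percentile 99.9, with 5 of 18 higher in VZ/SVZ, such as Klf2 (4.76-fold) and Dusp1 (4.70-fold), and Egr2 7.22-fold higher in the neurosphere. Interferon and MHC class I genes had a median of 0.47 at percentile 96.5, with 6 of 19 higher in VZ/SVZ, such as Isg15 (3.13-fold), and 2 in the neurosphere.

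Other signalling lists stayed near the middle of the random lists. Notch pathway genes had a median of -0.05 (percentile 63.6), with the Notch target Nrarp 10.3-fold higher in the neurosphere (-3.36 ± 0.22) and Rbpj, the pathway's DNA-binding factor, 3.23-fold higher in VZ/SVZ (1.69 ± 0.20). Wnt pathway genes had a median of -0.00 and a mean of 0.12 (percentile 53.4), and the median lay between -0.26 and 0.01 across scaling and background alternatives. Lgr5 was at least 7.11-fold and Tcf7 4.17-fold higher in the neurosphere, and Dkk3 at least 87.0-fold (another probe at 3.44) and the secreted Wnt modulator gene Sfrp2 11-fold higher in VZ/SVZ. Hedgehog pathway genes had a median of 0.30 (percentile 78.7), with Gli2 4.74-fold higher in VZ/SVZ and Gas1 4.13-fold higher in the neurosphere. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on both arrays, and the sex-linked list had a median of 0.83 (percentile 94.1). Eif2s3y was 5.19-fold higher in VZ/SVZ by its brightest probe (2.38 ± 0.21), with another probe at 6.72. Of the 32 lists ranked, 8 had medians above and 7 below the central 95% of their random lists. By that limit alone, 1.6 lists of independently drawn genes would lie outside. Members of a list need not vary independently and some lists share genes, so the 1.6 is no test of these counts.

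**Figure D2:**
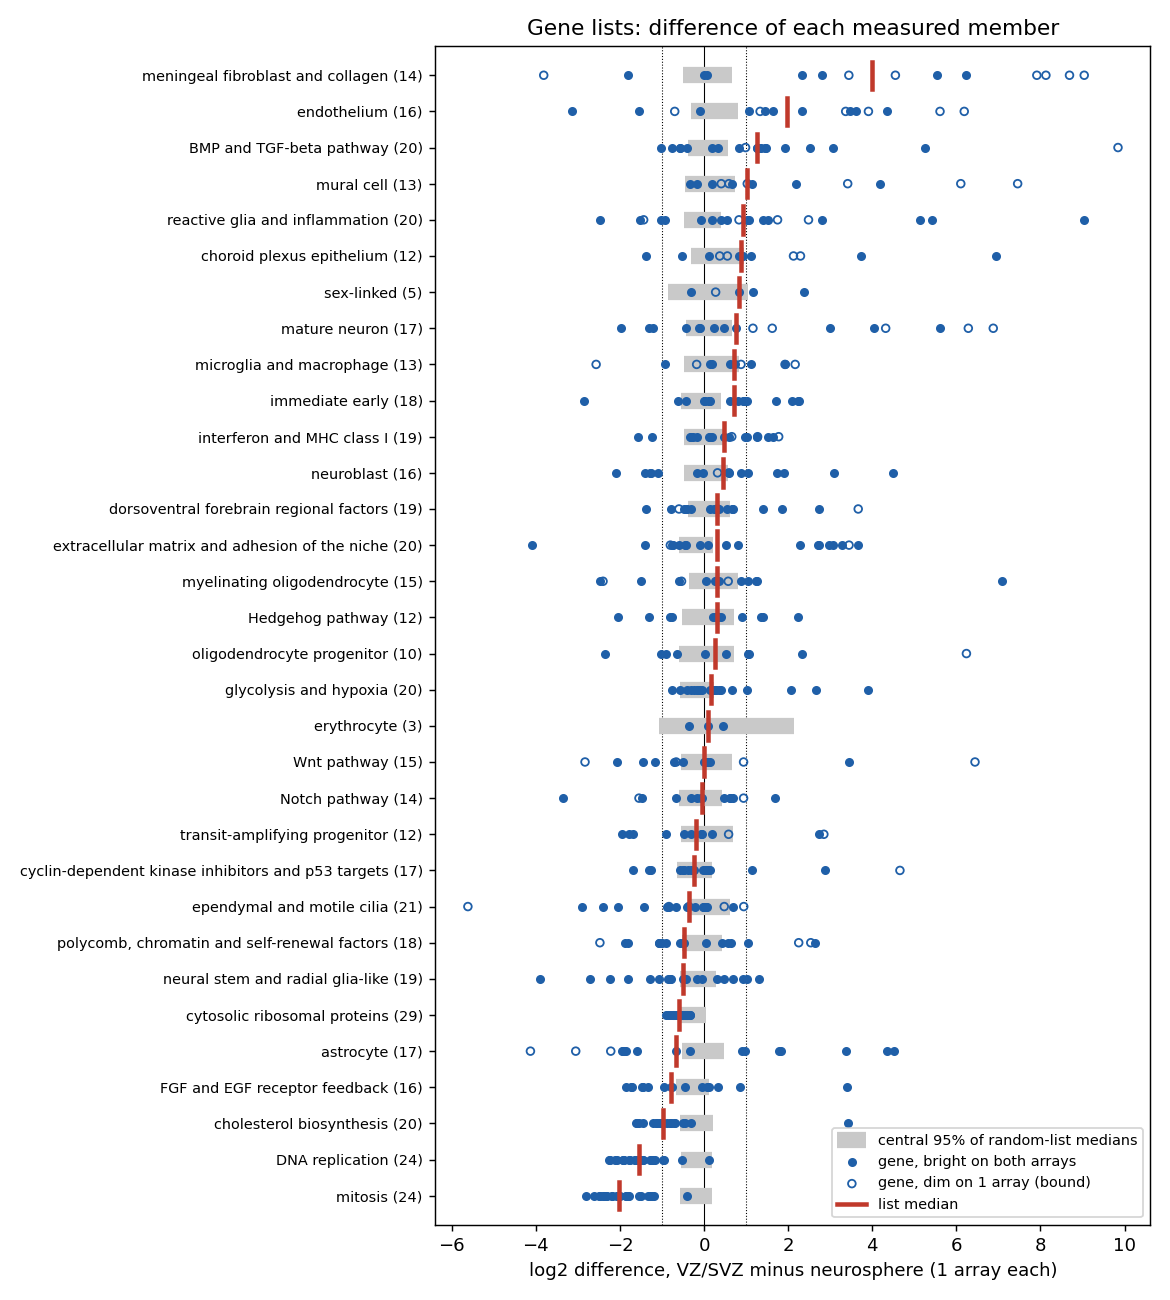
Log2 difference, VZ/SVZ minus neurosphere (x axis, dotted lines at 2-fold), of each measured gene in each list (filled points, bright on both arrays; open points, bounds of genes dim on 1 array), with the list median in red and the central 95% of random-list medians in grey. The mitosis and DNA replication medians lie at -2.03 and -1.55, and the meningeal fibroblast and collagen median at 4.0.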

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

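Spike-in control probes, which no comparison used, were bright on both arrays in part. Probe E1A_r60_a22 had a median signal of 256.7 on the neurosphere array and 281.7 on the VZ/SVZ array. Probe E1A_r60_a20 had 21.5 and 23.4. Both stood out because every spot was well above background, with negative control medians of 1.16 and 1.32. Probe E1A_r60_a104 was well above background on 33 of 35 spots of the neurosphere array and 17 of 35 of the VZ/SVZ array.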

How the results depend on the processing

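Measuring dim genes at their own value was an alternative chosen after seeing the data; the other alternatives were planned. Each group has 1 array, so no array could be left out, and no test was available to any alternative. No paired analysis was possible because each group has 1 array. Scaling to labelled spike-in probes was not run, since most of those probes were near background on both arrays. Signal over background limits the values of dim genes: normexp, whose offset shrinks differences of dim genes by construction, kept 2719 of the 7861 genes called at 2-fold, while quantile normalization kept 6246 and the median over a gene's probes 7097. Of the list medians computed under alternatives, 313 moved by less than their spread, 6 moved by more and 1 reversed. Of the percentiles, 326 stayed on the same side of the limits, 13 moved inside them and 13 moved outside. These counts pool settings that could change little, such as the authors' deposited values, which held the same intensities. For named genes, 1319 values moved by less than their spread, 335 moved by more and 1 reversed. Normexp moved 155 by more and 34 by less, and the median over probes moved 58 by more and 130 by less. The reversed value was that of Id2, at 0.45 with the median over its probes, which point in both directions. Unless a construction is named, the cause was not tested.

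Under normexp the counts were 1470 genes higher in VZ/SVZ and 1268 higher in the neurosphere, and Ecrg4 was at -2.21. List medians under normexp were 0.16 for choroid plexus, 0.30 for mural cells, -1.53 for mitosis, -1.19 for DNA replication and -0.75 for cholesterol synthesis; percentiles were 96.7 for mature neuron, 14.0 for astrocyte, 18.2 for ependymal, 99.5 for microglia and 1.64 for polycomb genes. With only probes bright on both arrays, which leaves fewer genes, 3171 genes were higher in VZ/SVZ. The astrocyte median then reversed to 0.28 (percentile 94.7), and percentiles were 79.6 for mature neuron, 10.1 for ependymal, 98.2 for choroid plexus and 96.8 for mural genes. With no filter on dim probes, which adds genes, 7670 genes were higher in VZ/SVZ, and percentiles were 99.5 for neuroblast and 99.3 for choroid plexus genes. With dim genes at their measured value the neuroblast percentile was 98.2. The 4-fold threshold left 1721 genes higher in VZ/SVZ and 623 in the neurosphere. Quantile normalization gave a ribosomal protein median of -0.40 and a neural stem percentile of 0.84. The median over a gene's probes gave percentiles of 3.91 for FGF and EGF feedback, 98.5 for glycolysis and 6.93 for ribosomal proteins. Without genes shared between lists, percentiles were 0.06 for neural stem and 97.8 for neuroblast genes. Against random lists not matched on level they were 1.04 for neural stem, 4.38 for ependymal, 98.85 for choroid plexus, 83.8 for matrix and 1.65 for polycomb genes. The ependymal percentile was 2.66 with the authors' deposited values and 2.5 with outlier spots kept. Fibroblast, endothelial, BMP and TGF-beta, mitosis, DNA replication and cholesterol lists kept their side of the limits under every alternative run.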

Other observations

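The tests of a lower share of neural cells, of array scaling and of dilution were chosen only after the results were seen, and the lists of posterior patterning, anterior patterning and fibroblast genes were written after the main results but before the values of their members were looked up, except Etv1, which a planned list also holds. Genes that pattern the neural tube along its length differed between the arrays. Besides Gbx2, Hoxa3, Irx1 and Irx2, the midbrain and hindbrain gene En2 was 16.5-fold higher in the neurosphere (-4.05) and Hoxa5 at least 16.4-fold higher. The posterior list held 30 genes, of which 14 were measured and the others were not well above background on either array. Of the 14 measured, 6 were higher in the neurosphere and 2, Hoxb3 (1.57) and Hoxc4 (at least 2.42-fold), in VZ/SVZ. The anterior list held 20 genes, of which 15 were measured. Of these, 7 were higher in VZ/SVZ, including Foxp1 (12-fold) and the forebrain gene Six3 (6.29-fold), and Lmo3 was 4.04-fold higher in the neurosphere.

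Fibroblast genes outside the planned list had the same direction as its collagens. Of 26 measured, 19 were higher in VZ/SVZ, among them the matrix cross-linking enzyme genes Lox (at least 63.7-fold) and Loxl1 (40.3-fold) and the transcription factor genes Foxc2 (at least 66.3-fold) and Tbx18 (16.2-fold). Fbln2 (4.78-fold), Fbln1 (3.06-fold) and Foxc1 (2.5-fold) were higher in the neurosphere.

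Several posterior patterning genes were bright on the neurosphere array. The median of the posterior list without the genes already seen was -0.51 (95% bootstrap interval -1.80 to 0.54), at percentile 0.68 of level-matched random lists. That of the anterior list was 0.96, at percentile 99.64. The posterior list still held Hoxa4, Hoxa5, Irx3 and Irx5, all higher in the neurosphere and of the same families as Hoxa3, Irx1 and Irx2, which were seen before. Hoxb3 and Hoxc4 had the opposite direction. Random lists draw genes independently, so percentile 0.68 is not independent support for the pattern that prompted the list. The planned list of forebrain regional factors did not stand apart (percentile 80.2), with 14 of 19 within 2-fold and Otx2 higher in the neurosphere. That the neurosphere cells may carry a more posterior identity than the VZ/SVZ cells is a hypothesis that depends on the processing: the posterior percentile was 0.02 with normexp and 0.11 with no filter on dim probes, but 10.9 with quantile normalization, 4.96 over genes bright on both arrays and 5.45 with the median over probes. The anterior percentile was 99.92 with no filter, 99.14 with the median over probes and 97.68 with quantile normalization, but 97.28 with normexp and 84.7 over genes bright on both arrays. The region the neurosphere came from, the culture itself and a mislabelled sample each stay open, since the labels say brain for both samples, and no technical explanation was tested beyond these alternatives.

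Collagen and meningeal fibroblast genes were far higher in VZ/SVZ. Fibroblast-like cells in the VZ/SVZ sample are a candidate source: the added list lay at percentile 100, and stayed there under each of the 5 alternatives run on it, and abundant fibroblast genes such as Dcn and Col1a1 had VZ/SVZ signals of 2292 and 1553. None of the added genes is in a planned list, but 17 of the 26 were also well above background on the neurosphere array. A smaller share of neural cells with no other change would raise the markers of every other cell type alike. The microglia median lay below the fibroblast and collagen median by 3.27, against ranges between quartiles of 0.96 for microglia and 6.85 for fibroblast members. Only a difference beyond the wider range was to count against this explanation, a limit hardly within reach, so the comparison cannot decide. Of the 20 microglia genes, 7 were also not well above background on either array, and a smaller share of neural cells stays open. Neural cells that took on mesenchymal genes in culture would show the same list and were not tested, and selection for β-galactosidase, as far as it was made, would remove fibroblasts that lack it.

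Mitosis and DNA replication genes were lower in VZ/SVZ. Array scaling and background correction do not account for it, since the smallest absolute mitosis median over those alternatives was 1.53. Dilution of neural stem cells by cells that do not divide, as the whole cause, would lower the neural stem list as much as the mitosis list. The medians differed by 1.53, within the range of 1.58 between quartiles of the neural stem members, which go both ways. That range describes single genes and not the median. The bootstrap intervals of the medians did not overlap, at -1.08 to 0.32 for neural stem and -2.31 to -1.70 for mitosis. These intervals argue against dilution as the whole cause, for the genes of these lists, although members need not vary independently. Dilution as part of the cause stays open. A slower cycle of the VZ/SVZ cells and a difference in culture also stay open, with 1 array per group.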
